A study of Homo sapiens with 9 samples.

How the data were processed

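The samples were circulating Tfh cells of adult kidney transplant recipients, 3 per group (DSA-, DSA+ ABMR- and DSA+ ABMR+), with no repeat libraries of a sample according to the series' design text. Per the labels, the cells were not stimulated and went from the sorter straight into lysis buffer. Total RNA came from a miRNeasy kit, strand-specific libraries from the pico-input SMARTer stranded kit, and reads were paired ends from a NextSeq 500. The markers of the sort gate are not given in the sources used here. Replicate numbers follow accession order and only name a sample, and the labels give no batch, date or pairing. The series' text gives 3 samples per group of patients, so p-values measure the spread between samples of different patients as far as that text goes.

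The authors deposited one file per sample with raw counts of read pairs per Ensembl gene, not normalized, followed by the 5 closing tallies that HTSeq writes. The submitters' processing notes name HISAT2 2.1.0, SAMtools 1.9, HTSeq 0.11.2, edgeR (no version), R 3.5.1 and GRCh38. The annotation release and the strand setting of the counting are not given in the sources used here, so values of antisense and overlapping genes are uncertain, as are those of paralogs that share reads. The files held 58302 gene IDs, of which 58039 matched GENCODE 29, used here for symbols, biotypes and coordinates, and 263 did not. Genes of chromosome Y, XIST and TSIX (519) were left out of every test and table because the samples are from patients, which left 57520 genes, 30429 of them with any count.

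Gene counts per library ranged from 17001823 to 26809573, and read pairs in the files from 58376330 to 73932799. Between 28.18% and 36.38% of read pairs were assigned to a gene. Group means in the order DSA-, DSA+ ABMR- and DSA+ ABMR+ were 34.37%, 31.04% and 27.6% with no feature, 10.15%, 16.13% and 8.95% not aligned, 16.53%, 18.42% and 24.96% with more than 1 alignment and 2.767%, 2.753% and 3.533% ambiguous, and 1.64% to 1.96% per library had a low alignment quality. The tallies were left out of the gene tests. A gene with no count in a group was given a bound from a floor of 3 counts over the group's total, which covers counting error only. Counts of read pairs without molecular identifiers are not independent molecules. Spearman correlations across genes were 0.915 to 0.931 within groups and 0.876 to 0.937 between groups, and the counts of libraries of 1 group differed by a chi-square of 43.3 to 89.5 per degree of freedom, so no library was treated as a duplicate.

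All work used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Genes were filtered with filterByExpr by group (minimum count 10, minimum total 15, CPM of 0.430), leaving 19381. One edgeR quasi-likelihood fit took all 9 samples with a mean per group (TMM factors 0.934 to 1.03, robust dispersion and quasi-likelihood estimation, common biological coefficient of variation 0.640, 6 residual degrees of freedom, median prior degrees of freedom 9.28). Its F-test was applied to each pair of groups and to both group coefficients together, with Benjamini-Hochberg adjusted p below 0.05 called. Mean and SD of CPM use the same TMM factors, and the standard error of a log2 fold change is its absolute value over the square root of F. Both comparisons with DSA- share the same 3 libraries, so no overlap or correlation between them was computed.

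The design, alternatives, gene lists and rule for named genes were fixed before the data were examined. The rule took, per comparison, the 12 largest increases and 12 largest decreases among genes that passed, or the 24 lowest p where fewer passed, leaving out pseudogenes, common germline presence or haplotype genes, receptor gene segments and X-inactivation escape genes. It further took, per list, the 2 members with the lowest p and the one with the highest mean CPM, of which the text prints those of the lists that passed and some of the T cell activation and plasma cell lists. CXCR5, PDCD1, ICOS, BCL6, IL21, CXCR3, CCR6, MKI67 and CD38 are always given. Some genes that the rule took are not reported here. Of the 35 lists written, 34 had at least 5 tested members, and the erythroid list was given as a sum only. Lists were tested with camera on log2 CPM (prior count 2, preset correlation 0.01), with camera under an estimated correlation and with fry beside it, each adjusted over the 34 lists. Under the estimated correlation 0 calls stayed in any comparison. Lists share members: 5 of the 20 Tfh identity genes and 1 of the 13 monocyte genes are in other lists. Members at 0 in 1 group were put at their bound as a check, which left every list median as it was. Sums of marker lists and library measures were compared with two-sided exact permutation tests, for which 3 against 3 libraries allow no p below 0.1.

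The fit was tested on simulated data. All 9 libraries were drawn from the mean CPM over all samples and the dispersions of the fit. For each pair of groups, 50 genes at each size were changed in 1 group of the pair, and all 9 libraries were fitted in 3 groups. In the order DSA+ ABMR- against DSA-, DSA+ ABMR+ against DSA- and DSA+ ABMR+ against DSA+ ABMR-, edgeR recovered 12%, 22% and 12% of 2-fold changes, 34%, 54% and 62% of 4-fold changes, 74%, 70% and 66% of 8-fold changes and 64%, 74% and 74% of 16-fold changes. False calls were 6 of 98, 9 of 119 and 5 of 112. DESeq2 made 47 false calls of 156, 50 of 181 and 42 of 173, and limma-voom 5 of 84, 7 of 103 and 4 of 96. A planted list gave camera adjusted p of 1.52e-11, 6.13e-06 and 5.79e-10 with the preset correlation, and 0.00481, 0.140 and 0.0176 with an estimated correlation. With either correlation 0 of the random lists passed. The simulated genes were drawn independently, while the estimated correlation in the real data reached 0.757 in the ribosomal protein list. The random lists therefore cannot tell how often camera with the preset correlation calls correlated lists falsely. The dispersions drawn from were those of the edgeR fit itself. The false calls of each tool thus hold for this simulation and do not give its share of false calls in the real data. By the recovery given above, changes of 2-fold are mostly out of reach with 3 libraries per group.

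The alternatives fixed in advance were other scaling factors (RLE and upper quartile), no filter and a filter at a mean of 5 CPM, DESeq2, limma-voom with quality weights, the edgeR likelihood ratio test, non-robust estimation, an adjusted p below 0.10, protein-coding genes only, only the 6 samples of a pair, other prior counts and leaving out each library. Chosen after seeing the data were the monocyte score (log2 summed CPM of the monocyte list) and the ribosomal RNA share as covariates, offsets for gene length and GC content, thinning to 16969331 counts, and leaving out DSA- replicate 3 and DSA+ ABMR- replicate 2 together. With 3 libraries per group, leaving out 1 leaves 2 in its group. Groups of 3 were not searched for outlying values.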

Results

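Total RNA was sequenced from circulating T follicular helper (Tfh) cells, the blood counterpart of the CD4 T cells that help B cells make antibody, of adult kidney transplant recipients. The 9 libraries fall into 3 groups of 3. Recipients in the DSA- group had no donor-specific HLA antibodies (DSA). Those in the DSA+ ABMR- group had the antibodies without antibody-mediated rejection (ABMR), and those in the DSA+ ABMR+ group had both. Gene counts came to 24728435, 23327780 and 20854973 in the DSA- libraries (replicates 1 to 3), 17795913, 17001823 and 23398863 in the DSA+ ABMR- libraries, and 26809573, 23300075 and 22409729 in the DSA+ ABMR+ libraries. Expression is given in CPM (counts scaled to library size) as mean ± SD over 3 libraries, and coordinates are those of GRCh38 (GENCODE 29). Fold changes and adjusted p come from the edgeR quasi-likelihood test over 19381 genes with the Benjamini-Hochberg adjustment, and SE is the standard error of a log2 fold change.

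The composition of the libraries was measured first, from marker lists fixed before the counts were opened. The 13 monocyte markers together took 14221 ± 1592 CPM in the DSA- group, 5294 ± 3015 CPM in the DSA+ ABMR- group and 5461 ± 1615 CPM in the DSA+ ABMR+ group. Lysozyme (LYZ) alone stood at 4667 ± 812, 1799 ± 1150 and 1969 ± 449 CPM in the same order. The 14 T cell lineage markers summed to 1389 ± 191, 2152 ± 755 and 2577 ± 434 CPM, and the 20 Tfh identity genes to 965.4 ± 92.3, 1481 ± 470 and 1740 ± 316 CPM. The monocyte sum thus lay above the T cell lineage sum in the mean of every group. It did so in every library but DSA+ ABMR- replicate 3 (2804 against 2983 CPM). Changes of single genes between the groups can therefore not be placed in the Tfh cells alone. Neutrophil markers summed to 508.7 ± 95.4, 163.6 ± 90.9 and 147.8 ± 48.2 CPM, and CD8 and NK cell markers to 603.8 ± 130, 268.3 ± 100 and 279.9 ± 148 CPM. Single genes carried much of both sums. In the DSA- libraries CSF3R took 400.4, 460.8 and 588.9 of 422.4, 492.5 and 611.1 CPM of the neutrophil sums. TYROBP, which is in the monocyte list too, took 359.8, 347.3 and 316.1 of 732.1, 472.5 and 607 CPM of the CD8 and NK sums. These sums are thus not measures of separate cell types. Markers of gamma delta T and MAIT cells summed to 86.19 ± 36.8, 201.8 ± 79.1 and 165.2 ± 50.3 CPM. B cell markers came to 89.7 ± 34.3, 147.5 ± 79.3 and 155 ± 64.1 CPM, dendritic cell markers to 210.4 ± 24.4, 141.5 ± 71.5 and 112.5 ± 9.60 CPM, and plasma cell markers to 270.9 ± 17.3, 257 ± 44.7 and 303.4 ± 72.8 CPM. Platelet markers (43.3, 25.02 and 22.9 CPM) and erythroid markers (17.86, 20.79 and 26.57 CPM) were low in all groups. In two-sided exact permutation tests, where 3 against 3 libraries allow no p below 0.1, the monocyte, neutrophil, Tfh identity, gamma delta T and MAIT, and CD8 and NK sums reached 0.1 in both comparisons with the DSA- group. The T cell lineage sum gave an exact p of 0.2 for the DSA+ ABMR- group and 0.1 for the DSA+ ABMR+ group, and the B cell sum gave 0.5 and 0.3. Over the 75 such tests of 25 measures the lowest adjusted p was 0.3.

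**Figure D1:**
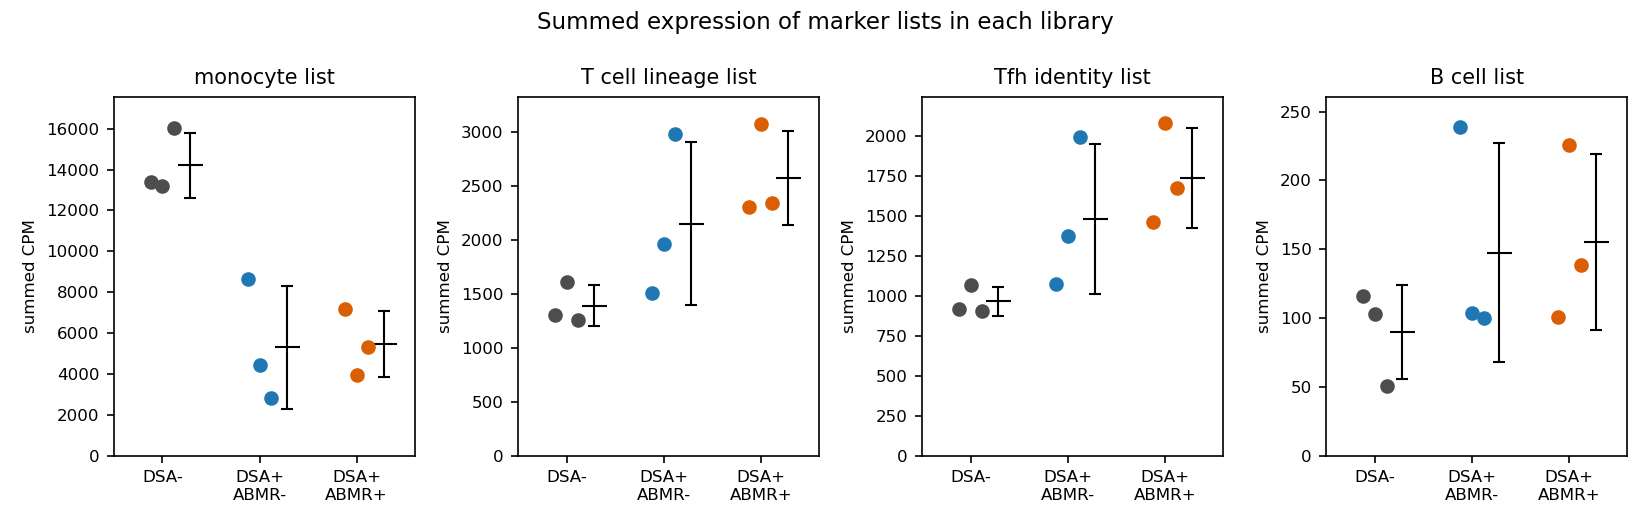
Summed expression (CPM) of the monocyte, T cell lineage, Tfh identity and B cell marker lists in each of the 9 libraries; points are libraries and the bars show the mean and SD of each group of 3. The monocyte sums of the DSA- libraries (13190 to 16054 CPM) lie above those of the DSA+ ABMR- (2804 to 8646 CPM) and DSA+ ABMR+ (3932 to 7151 CPM) libraries.

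Measures of library quality also moved with the groups. Ribosomal RNA genes, with those of mitochondria and pseudogenes included, took 3.604% ± 0.613 of the gene counts in the DSA- group, 4.537% ± 0.728 in the DSA+ ABMR- group and 6.497% ± 0.802 in the DSA+ ABMR+ group (exact permutation p = 0.2, and 0.1 for both comparisons of the last group). All mitochondrial genes took 4.644%, 5.194% and 5.83%, and the mitochondrially encoded list 26597, 24792 and 26506 CPM. The mitochondrial part of the ribosomal RNA share was not separated. Protein-coding genes took 83.63% ± 0.924, 80.99% ± 0.847 and 79.86% ± 1.81. Read pairs with more than 1 alignment came to 16.53% ± 3.75, 18.42% ± 3.01 and 24.96% ± 3.84. Nuclear retained RNAs such as MALAT1 and NEAT1 summed to 66455 ± 16234, 71355 ± 7538 and 49748 ± 1350 CPM, and immediate early and heat shock genes to 24077 ± 3170, 21265 ± 1656 and 19353 ± 2816 CPM. In the multidimensional scaling, DSA- replicate 3 lay farthest out on the first dimension (-2.78) and DSA+ ABMR- replicate 2 on the second (2.99).

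The first comparison, DSA+ ABMR- against DSA-, asks how the sorted samples, monocyte RNA included, differ with donor-specific antibody in the absence of rejection. TCF7 (ENSG00000081059, chr5:134114711-134151865), which encodes a transcription factor of T cells, rose from 263 ± 70.0 to 530 ± 158 CPM (log2 fold change 1.01, SE 0.23, adjusted p = 0.0444), and its relative LEF1 from 123 ± 31.5 to 269 ± 64.0 CPM (1.13, SE 0.22, adjusted p = 0.0232). In the 9 fits that leave out 1 library, TCF7 passed in 3 (adjusted p up to 0.129) and LEF1 in 6 (up to 0.0751). MYC rose from 46.6 ± 4.46 to 98.7 ± 15.8 CPM (1.08, adjusted p = 0.0203). The early activation antigen CD69 rose from 301 ± 42.3 to 590 ± 210 CPM (0.97, adjusted p = 0.0373). The long noncoding RNA LINC00402 (ENSG00000235532, chr13:74231457-74259976) rose from 3.44 ± 1.37 to 26.2 ± 11.6 CPM, with a log2 fold change of 2.93 (SE 0.40, adjusted p = 0.0102). Among the other genes with the largest increases were CDK5R1 (2.67), C5orf63 (2.67), IGFBP4 (2.52), GCNT4 (2.39), MORN3 (2.30), NDC80 (2.20), ZNF483 (2.14), HPCAL4 (1.997), PBX4 (1.97) and TCEA3 (1.73), with adjusted p from 0.0165 to 0.0478. Without DSA- replicate 2, the fold changes of C5orf63, MORN3 and HPCAL4 moved by a factor of over 1.5, to log2 values of 3.45, 2.945 and 2.682. AC009163.6 had no count in the DSA- group and 1.63 ± 0.491 CPM in the DSA+ ABMR- group, a log2 fold change of at least 5.16 from the floor of 3 counts.

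PROK2 (ENSG00000163421, chr3:71771656-71785206), a chemokine-like factor of neutrophils and monocytes, was among the largest decreases and fell from 31.2 ± 3.46 to 4.52 ± 2.06 CPM (log2 fold change -2.79, SE 0.47, adjusted p = 0.0165). The metalloreductase gene STEAP4 fell from 36.1 ± 8.61 to 6.30 ± 2.66 CPM (-2.52, adjusted p = 0.0162), and PADI4, whose enzyme citrullinates histones in neutrophils, from 27.0 ± 6.71 to 6.95 ± 1.9 CPM (-1.96, adjusted p = 0.0406). The receptor gene CSF1R fell from 223 ± 59.0 to 70.5 ± 14.8 CPM (-1.66, SE 0.34, adjusted p = 0.0384). MSRB2 (-3.48), SRD5A3 (-3.04), CLTCL1 (-2.75), FBN2 (-2.46), FAM20C (-2.35), RUSC2 (-2.16), ADAMTSL4 (-2.08) and CCRL2 (-2.05) completed the 12 largest decreases together with the antisense gene AC090617.3 (-2.81), which is uncertain because the strand setting of the counting is not given. MSRB2 moved to -4.16 without DSA+ ABMR- replicate 1 and AC090617.3 to -2.11 without DSA- replicate 3 (adjusted p = 0.233). The ectonucleotidase gene ENTPD1 fell from 68.8 ± 8.61 to 25.9 ± 9.16 CPM (-1.41, adjusted p = 0.025). Beside these changes stand the monocyte sums of 14221 CPM in the DSA- group and 5294 CPM in the DSA+ ABMR- group.

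Of the Tfh identity list, TCF7 alone passed gene by gene in this comparison. The chemokine receptor gene CXCR5, which defines the lineage, stood at 93.6 ± 36.5 against 22.2 ± 14.7 CPM (log2 fold change 2.08, SE 0.53, adjusted p = 0.0905). PDCD1 stood at 10.7 ± 4.66 against 2.47 ± 2.29 CPM (2.12, adjusted p = 0.179), ICOS at 65.7 ± 33.2 against 27.6 ± 15.8 CPM (1.25, adjusted p = 0.165), and TOX at 35.4 ± 12.2 against 14.3 ± 5.18 CPM (1.31, adjusted p = 0.0508). BCL6, the master regulator of Tfh cells that monocytes express too, stood lower, at 113 ± 43.9 against 240 ± 61.6 CPM (-1.09, adjusted p = 0.0819). Log2 fold changes were 0.39 for CXCR3, 0.65 for CCR6, 0.29 for MKI67 and 0.46 for CD38 (adjusted p = 0.614 or more). IL21 was near the detection limit, at 0.145 ± 0.203 against 0.180 ± 0.311 CPM (-0.27). CD4 stood at 257 ± 9.40 against 318 ± 47.3 CPM (-0.30, adjusted p = 0.372). Without DSA- replicate 2, CXCR5 (adjusted p = 0.0312) and ICOS (0.0386) passed, and without DSA+ ABMR- replicate 1 BCL6 (0.0169) and TOX (0.0151) did. TOX passed without DSA+ ABMR+ replicate 2 as well (0.0463). The adjusted p of CXCR5 lay between 0.0312 and 0.288 over the 9 fits that leave out 1 library. Fold changes moved by a factor of over 1.5 for some genes, given here as the log2 values reached. These were CXCR5 (2.776) without DSA- replicate 2, PDCD1 (3.007) without DSA- replicate 3, CD38 (1.504) without DSA- replicate 1 and IL21 (-2.39) without DSA+ ABMR- replicate 3. Signs turned for IL21 (4.76) and MKI67 (-0.05) without DSA- replicate 2, for IL21 (0.28) without DSA+ ABMR- replicate 1, for IL21 (0.08) and MKI67 (-0.09) without DSA+ ABMR- replicate 2, and for CXCR3 (-0.20) without DSA+ ABMR- replicate 3.

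In all, 333 genes passed at an adjusted p below 0.05 in the DSA+ ABMR- against DSA- comparison, 122 higher and 211 lower (63.36% lower; 43.58% with upper-quartile factors). More were higher than lower without DSA- replicate 2 (96 and 84), DSA+ ABMR- replicate 2 (31 and 30) or DSA+ ABMR- replicate 3 (25 and 16). DESeq2 called 1307, limma-voom 836 and the edgeR likelihood ratio test 826. The count rested on single libraries: it was 58 without DSA- replicate 1, 180 without DSA- replicate 2, 45 without DSA- replicate 3, 61 without DSA+ ABMR- replicate 2 and 41 without DSA+ ABMR- replicate 3. It was 809 without DSA+ ABMR- replicate 1, 533 without DSA+ ABMR+ replicate 2 and 213 without DSA+ ABMR+ replicate 3. Of the 34 passing genes taken for naming, between 5 and 33 still passed without 1 library. With the monocyte score as a covariate 12 genes passed, and with the ribosomal RNA share 2. Both covariates followed the groups, so calls lost with them, here and below, do not tell a cause. Monocyte sums were 13190 to 16054 CPM in DSA-, 2804 to 8646 CPM in DSA+ ABMR- and 3932 to 7151 CPM in DSA+ ABMR+ libraries. Ribosomal RNA shares were 3.001% to 4.226%, 3.752% to 5.191% and 5.999% to 7.422% in the same order. Without both libraries that lay farthest out, 0 genes passed and 2144 had an unadjusted p below 0.05.

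Of the 34 gene lists tested with camera, 8 passed for DSA+ ABMR- against DSA-, with Tfh, naive and central memory, T cell lineage and ribosomal protein genes higher and monocyte, neutrophil, glycolysis and NF-kB genes lower. In the Tfh identity list (median log2 fold change 1.21, adjusted p = 0.000445), 1 of 20 genes rose over all genes, TCF7. Adjusted over the list alone, 14 rose and 2 fell, and the list gave an adjusted p = 0.487 with an estimated correlation. The naive and central memory list had a median of 0.91 (adjusted p = 0.000103; adjusted p = 0.487 with an estimated correlation). Of its 12 genes 4 rose, among them LEF1 and MYC, and 8 adjusted over the list alone, while IL7R stood at 878 ± 322 against 462 ± 231 CPM. In the T cell lineage list (median 0.86, adjusted p = 0.000506; adjusted p = 0.814 with an estimated correlation), 1 of 14 genes rose, and 8 adjusted over the list alone, with CD3G at 104 ± 36.0 against 56.2 ± 3.00 CPM (adjusted p = 0.0648; 0.00724 without DSA+ ABMR- replicate 1). The 24 ribosomal protein genes had a median of 0.41 (adjusted p = 6.18e-05; adjusted p = 0.814 with an estimated correlation) and 0 passed singly or adjusted over the list alone, RPS6 standing at 1490 ± 175 against 1010 ± 226 CPM.

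The monocyte list had a median log2 fold change of -1.38 in the DSA+ ABMR- against DSA- comparison (adjusted p = 2.64e-07; adjusted p = 0.643 with an estimated correlation). Of its 13 genes 1 fell, CSF1R, and 9 adjusted over the list alone, CD14 standing at 81.9 ± 34.5 against 229 ± 45.3 CPM (adjusted p = 0.0635). The neutrophil list (median -1.60, adjusted p = 0.00708; adjusted p = 0.487 with an estimated correlation) had 0 of 6 genes past the threshold and 2 adjusted over the list alone, CSF3R at 155 ± 88.8 against 483 ± 96.3 CPM and MPO at 3.85 ± 1.30 against 14.9 ± 4.90 CPM. Among 17 glycolysis genes (median -0.53, adjusted p = 0.00551; adjusted p = 0.487 with an estimated correlation), ALDOA fell from 444 ± 37.2 to 261 ± 42.1 CPM (adjusted p = 0.0312) and 8 fell adjusted over the list alone, GAPDH standing at 578 ± 120 against 946 ± 169 CPM. Without DSA+ ABMR- replicate 1, CD14 (adjusted p = 0.027), CSF3R (0.011) and GAPDH (0.0167) passed, and without DSA+ ABMR+ replicate 2 CD14 (0.0209) and MPO (0.0422) did. The NF-kB list went lower by its median of -0.81 (adjusted p = 0.0111; adjusted p = 0.814 with an estimated correlation). Of its 15 genes 2 fell and 1 rose, and 7 fell and 2 rose adjusted over the list alone. NFKBIE, an inhibitor of NF-kB, fell from 118 ± 10.7 to 49.7 ± 11.1 CPM (-1.25, adjusted p = 0.0198), and BIRC3, an inhibitor of apoptosis, rose from 208 ± 32.0 to 376 ± 21.4 CPM (0.86, adjusted p = 0.0219). The NF-kB call was lost without DSA- replicate 3 (adjusted p = 0.127) and without DSA+ ABMR- replicate 3 (adjusted p = 0.0951), against 0.00269 to 0.127 over the 9 fits that leave out 1 library. With the monocyte score as a covariate none of the 8 calls stayed, and without both libraries that lay farthest out the ribosomal protein call was lost (adjusted p = 0.067). The directional fry test passed for the neutrophil and glycolysis lists only (adjusted p = 0.0135 for both).

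**Figure D2:**
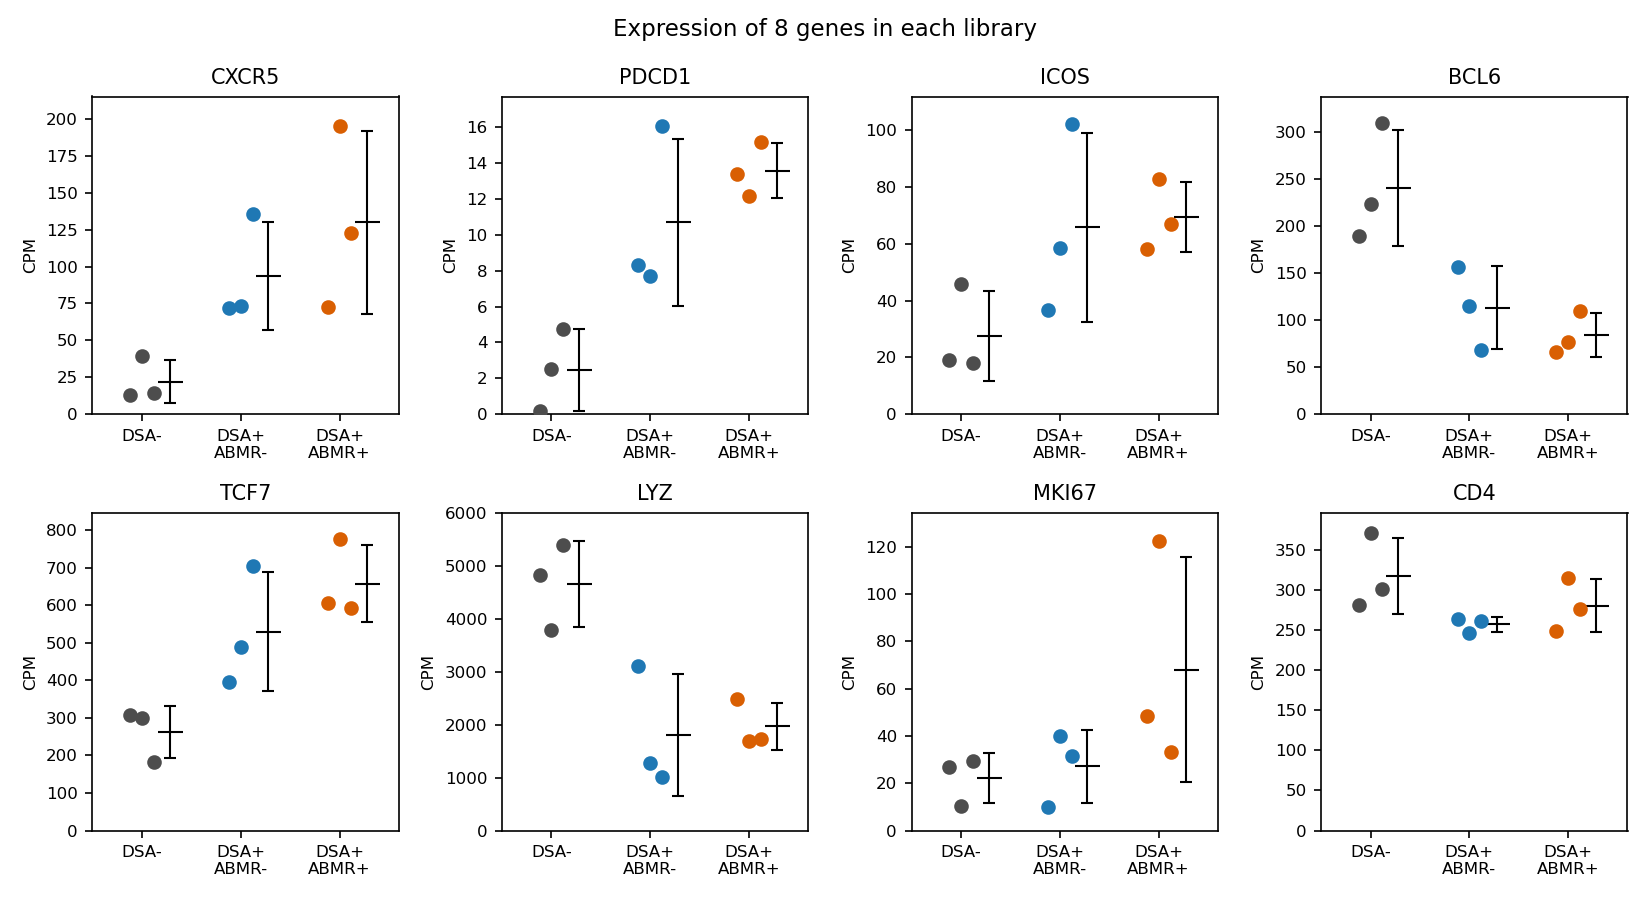
Expression (CPM) of CXCR5, PDCD1, ICOS, BCL6, TCF7, LYZ, MKI67 and CD4 in each of the 9 libraries; points are libraries and the bars show the mean and SD of each group of 3. CXCR5 averages 22.2 CPM in DSA-, 93.6 CPM in DSA+ ABMR- and 130 CPM in DSA+ ABMR+ libraries.

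The comparison of DSA+ ABMR+ with DSA- asks how the sorted samples differ where antibody comes with rejection. CXCR5 (ENSG00000160683, chr11:118883766-118897799) rose from 22.2 ± 14.7 to 130 ± 61.9 CPM, a log2 fold change of 2.55 (SE 0.54, adjusted p = 0.0466). TCF7 rose from 263 ± 70.0 to 658 ± 103 CPM (1.32, SE 0.23, adjusted p = 0.0177). BCL6 (ENSG00000113916, chr3:187721377-187745727), a transcriptional repressor of Tfh cells that monocytes also express, fell from 240 ± 61.6 to 84.1 ± 23.1 CPM (-1.51, SE 0.30, adjusted p = 0.0256). PDCD1 stood at 13.6 ± 1.51 against 2.47 ± 2.29 CPM (2.46, SE 0.77, adjusted p = 0.105) and ICOS at 69.3 ± 12.4 against 27.6 ± 15.8 CPM (1.33, adjusted p = 0.119). CD3E of the T cell receptor complex rose from 150 ± 26.2 to 310 ± 75.0 CPM (1.05, adjusted p = 0.0321) and the costimulatory receptor CD28 from 87.6 ± 31.7 to 217 ± 46.4 CPM (1.31, adjusted p = 0.0492). CD4 stood at 280 ± 33.1 against 318 ± 47.3 CPM (-0.18, adjusted p = 0.636). The other markers did not pass: IL21 (0.739 ± 0.708 against 0.180 ± 0.311 CPM), CXCR3 (log2 fold change 0.26), CCR6 (0.58) and CD38 (1.24), with adjusted p of 0.532 or more. PDCD1 moved to 3.35 without DSA- replicate 3, CD38 to 2.27 without DSA- replicate 1, and IL21 from 2.004 to 7.04 without DSA- replicate 2 and to 1.14 without DSA+ ABMR+ replicate 3.

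The CXCR5 call in DSA+ ABMR+ against DSA- was lost in 6 of the 9 fits that leave out 1 library: without DSA- replicate 1 (adjusted p = 0.127) or 3 (0.182), DSA+ ABMR- replicate 1 (0.063) or 2 (0.076), and DSA+ ABMR+ replicate 2 (0.120) or 3 (0.124), against a lowest adjusted p of 0.0241. Its log2 fold change stayed between 2.13 and 3.25 in these fits and was 1.33 (SE 0.65, adjusted p = 1.00) with the monocyte score as a covariate. The BCL6 call was lost without DSA- replicate 3 (adjusted p = 0.082), DSA+ ABMR+ replicate 1 (0.062) or DSA+ ABMR+ replicate 2 (0.091), against a lowest adjusted p of 0.00149. ICOS passed without DSA- replicate 2 (adjusted p = 0.0249) and without DSA+ ABMR- replicate 3 (0.0391), and CXCR3 turned sign without DSA- replicate 2 (-0.04).

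Among the largest increases from DSA- to DSA+ ABMR+, TOP2A, which encodes a DNA topoisomerase of dividing cells, rose from 4.08 ± 1.08 to 27.0 ± 22.1 CPM (log2 fold change 2.72, SE 0.61, adjusted p = 0.0376). The TOP2A call held in 3 of the 9 fits that leave out 1 library, and without DSA+ ABMR+ replicate 2 the value was 1.805 (adjusted p = 0.126). The DNA polymerase gene POLQ rose from 0.604 ± 0.330 to 6.44 ± 2.46 CPM (3.40, adjusted p = 0.0326). MKI67 stood at 68.1 ± 47.6 against 22.2 ± 10.4 CPM (1.61, adjusted p = 0.232), and at 0.88 without DSA+ ABMR+ replicate 2. LINC00402 rose to 28.5 ± 8.92 CPM (3.05, SE 0.40, adjusted p = 0.0103). FUNDC1 (3.86), C5orf63 (2.62), COL6A3 (2.53), IGFBP4 (2.35) and the histone gene HIST1H2BM (2.27), which shares reads with its paralogs, rose as well, with adjusted p from 0.0339 to 0.0448. COL6A3 moved to 1.89 (adjusted p = 0.170) without DSA+ ABMR+ replicate 2, and C5orf63 to 3.39 and HIST1H2BM to 2.96 without DSA- replicate 2. COL5A3 rose by 3.17 with overlapping groups (16.8 ± 12.7 against 1.88 ± 0.953 CPM), and so did the immunoglobulin light chain gene IGKC by 2.07 (17.8 ± 11.1 against 4.25 ± 1.63 CPM, adjusted p = 0.0487). AC009163.6 had 1.51 ± 0.526 CPM against no count, a log2 fold change of at least 5.07, and MALINC1 (3.28) is antisense and uncertain for the reason given above.

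In DSA+ ABMR+ relative to DSA- libraries, BHLHE40 (ENSG00000134107, chr3:4979116-4985323), a transcription factor of T cells and myeloid cells, fell from 728 ± 169 to 255 ± 36.0 CPM (log2 fold change -1.51, SE 0.21, adjusted p = 0.0103). CD83, a maturation marker of dendritic cells that activated lymphocytes carry too, fell from 650 ± 225 to 171 ± 7.77 CPM (-1.93, SE 0.32, adjusted p = 0.0191). NFKBIE fell from 118 ± 10.7 to 42.4 ± 9.92 CPM (-1.48, adjusted p = 0.0103), ENTPD1 from 68.8 ± 8.61 to 31.1 ± 10.1 CPM (-1.15, adjusted p = 0.0423) and MPO from 14.9 ± 4.90 to 2.75 ± 1.28 CPM (-2.43, adjusted p = 0.0253). The phospholipase gene PLA2G16 fell from 5.75 ± 0.516 to 0.488 ± 0.0126 CPM (-3.54, adjusted p = 0.0173) and PROK2 from 31.2 ± 3.46 to 4.40 ± 2.37 CPM (-2.83, adjusted p = 0.0127). AL137918.1 had no count in the DSA+ ABMR+ group, a log2 fold change of -6.41 or below from the floor of 3 counts. SPRY2 had none there either, against 2.92 ± 4.34 CPM in the DSA- group, and passed in 3 of the 9 fits that leave out 1 library (adjusted p = 0.263 without DSA- replicate 3). NTSR1 (-5.09), AC245128.3 (-3.38), AL391832.2 (-3.29), SPRED2 (-3.17), IFIT1 (-3.16), and the overlapping or antisense transcripts AC067852.3 (-2.80) and AC090617.3 (-3.46), whose strand is uncertain, were also among the 12 largest decreases. NTSR1 moved to -4.46 (adjusted p = 0.070) without DSA+ ABMR+ replicate 1 and to -7.63 without replicate 3 of that group, AC245128.3 to -4.12 without DSA+ ABMR+ replicate 1, and AC090617.3 to -2.755 (adjusted p = 0.119) without DSA- replicate 3. Beside them stand monocyte sums of 14221 CPM in the DSA- group and 5461 CPM in the DSA+ ABMR+ group.

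In all, 508 genes passed in DSA+ ABMR+ against DSA-, 177 higher and 331 lower (65.16% lower; 51.56% with upper-quartile factors). DESeq2 called 1660, limma-voom 1018 and the likelihood ratio test 1234. The count was 179 without DSA- replicate 1, 65 without DSA- replicate 3, 65 without DSA+ ABMR+ replicate 2 and 63 without DSA+ ABMR+ replicate 3. It was 898 without DSA+ ABMR- replicate 1 and 1053 without DSA+ ABMR- replicate 3. Of the 39 passing genes taken for naming, between 6 and 39 still passed without 1 library. With the monocyte score as a covariate 1 gene passed, with the ribosomal RNA share 0, and without both libraries that lay farthest out 0, with 2579 at an unadjusted p below 0.05. Ribosomal RNA shares were 3.604% and 6.497% in the DSA- and DSA+ ABMR+ groups.

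Of the 34 lists, 11 passed with camera in DSA+ ABMR+ against DSA-. Ribosomal protein genes had a median log2 fold change of 0.62 (adjusted p = 1.86e-08; adjusted p = 0.447 with an estimated correlation). Of 24, RPS6 (from 1010 ± 226 to 1735 ± 243 CPM, adjusted p = 0.033) and RPL32 (from 440 ± 99.5 to 701 ± 41.7 CPM, adjusted p = 0.0464) rose, and 22 rose adjusted over the list alone. The T cell lineage list had a median of 1.05 (adjusted p = 8.88e-07; adjusted p = 0.447 with an estimated correlation), with 6 of 14 genes risen and 11 adjusted over the list alone. The Tfh identity list had a median of 1.42 (adjusted p = 4.81e-06; adjusted p = 0.434 with an estimated correlation). Of its 20 genes 4 rose, CXCR5 and TCF7 among them, and BCL6 fell, while 13 rose and 1 fell adjusted over the list alone. The naive and central memory list had a median of 1.00 (adjusted p = 2.62e-05; adjusted p = 0.434 with an estimated correlation), with 5 of 12 genes risen and 6 adjusted over the list alone. MYC rose from 46.6 ± 4.46 to 101 ± 21.8 CPM (adjusted p = 0.0175) and IL7R stood at 858 ± 184 against 462 ± 231 CPM. The proliferation list had a median of 1.55 (adjusted p = 0.000369; adjusted p = 0.447 with an estimated correlation), with 1 of 22 genes risen, TOP2A, and 4 adjusted over the list alone. TYMS stood at 7.06 ± 4.72 against 0.893 ± 0.364 CPM (adjusted p = 0.0526, with 0.0265 and 0.0341 without DSA+ ABMR- replicates 1 and 3) and PCNA at 53.5 ± 10.8 against 43.4 ± 3.96 CPM. The log2 fold change of TYMS moved from 2.975 to 2.277 (adjusted p = 0.310) without DSA+ ABMR+ replicate 2. The B cell list had a median of 0.76 (adjusted p = 0.0375; adjusted p = 0.612 with an estimated correlation) and 0 of 14 genes past the threshold singly or adjusted over the list alone. MS4A1, which encodes CD20, stood at 34.6 ± 14.3 against 19.95 ± 8.83 CPM. The B cell call was lost without DSA- replicate 3 (adjusted p = 0.240) and without DSA+ ABMR+ replicate 2 (0.305), over a range of 0.00907 to 0.305.

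Monocyte genes had a median log2 fold change of -1.25 in DSA+ ABMR+ against DSA- (adjusted p = 8.88e-07; adjusted p = 0.447 with an estimated correlation). None of the 13 passed singly and 9 fell adjusted over the list alone, VCAN standing at 1430 ± 408 against 4370 ± 1084 CPM and FCN1 at 794 ± 223 against 2134 ± 385 CPM. Both passed without DSA+ ABMR- replicate 1 (adjusted p = 0.0121 and 0.0081) and replicate 3 (0.0107 and 0.00617). The NF-kB list (median -0.93, adjusted p = 0.000367; adjusted p = 0.447 with an estimated correlation) had 4 of 15 genes fallen, NFKBIE and CD83 among them, and adjusted over the list alone 8 fell and 1 rose. The neutrophil list (median -0.86, adjusted p = 0.0279; adjusted p = 0.434 with an estimated correlation) had 1 of 6 genes fallen, MPO, and 2 adjusted over the list alone, and its call was lost without DSA- replicate 2 (adjusted p = 0.0596, the highest in a range from 0.0119), and its median was -1.61 without DSA+ ABMR+ replicate 2. In the Th1 and Tfh1 list (median -0.75, adjusted p = 0.0279; adjusted p = 0.447 with an estimated correlation), BHLHE40 fell as 1 of 15 genes and 2 fell adjusted over the list alone, RUNX3 standing at 113 ± 8.63 against 174 ± 35.2 CPM. Its call was lost without DSA- replicate 1 (adjusted p = 0.0546) or 3 (0.171) and without DSA+ ABMR+ replicate 2 (0.0531) or 3 (0.080), over a range of 0.00154 to 0.171. The type I interferon list had a median of -0.36 (adjusted p = 0.0279; adjusted p = 0.612 with an estimated correlation). IFIT1 fell from 7.43 ± 3.98 to 0.821 ± 0.311 CPM (adjusted p = 0.031) and MX2 from 176 ± 24.6 to 95.6 ± 18.3 CPM (adjusted p = 0.0253), the 2 of 23 genes that passed, and adjusted over the list alone 5 fell and 1 rose. This call was lost without DSA- replicate 1 (adjusted p = 0.172), DSA+ ABMR- replicate 3 (0.062) or DSA+ ABMR+ replicate 2 (0.471), over a range of 0.00684 to 0.471, and was 0.053 with the 6 samples of this pair alone. With the monocyte score as a covariate the naive and central memory (adjusted p = 0.0301) and Th1 and Tfh1 (0.0413) calls stayed and the other 9 were lost. Without both libraries that lay farthest out the Th1 and Tfh1 (0.146) and B cell (0.245) calls were lost. The directional fry test passed for the Tfh identity and naive and central memory lists (adjusted p = 0.0354 for both) and the neutrophil list (0.028).

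**Figure D3:**
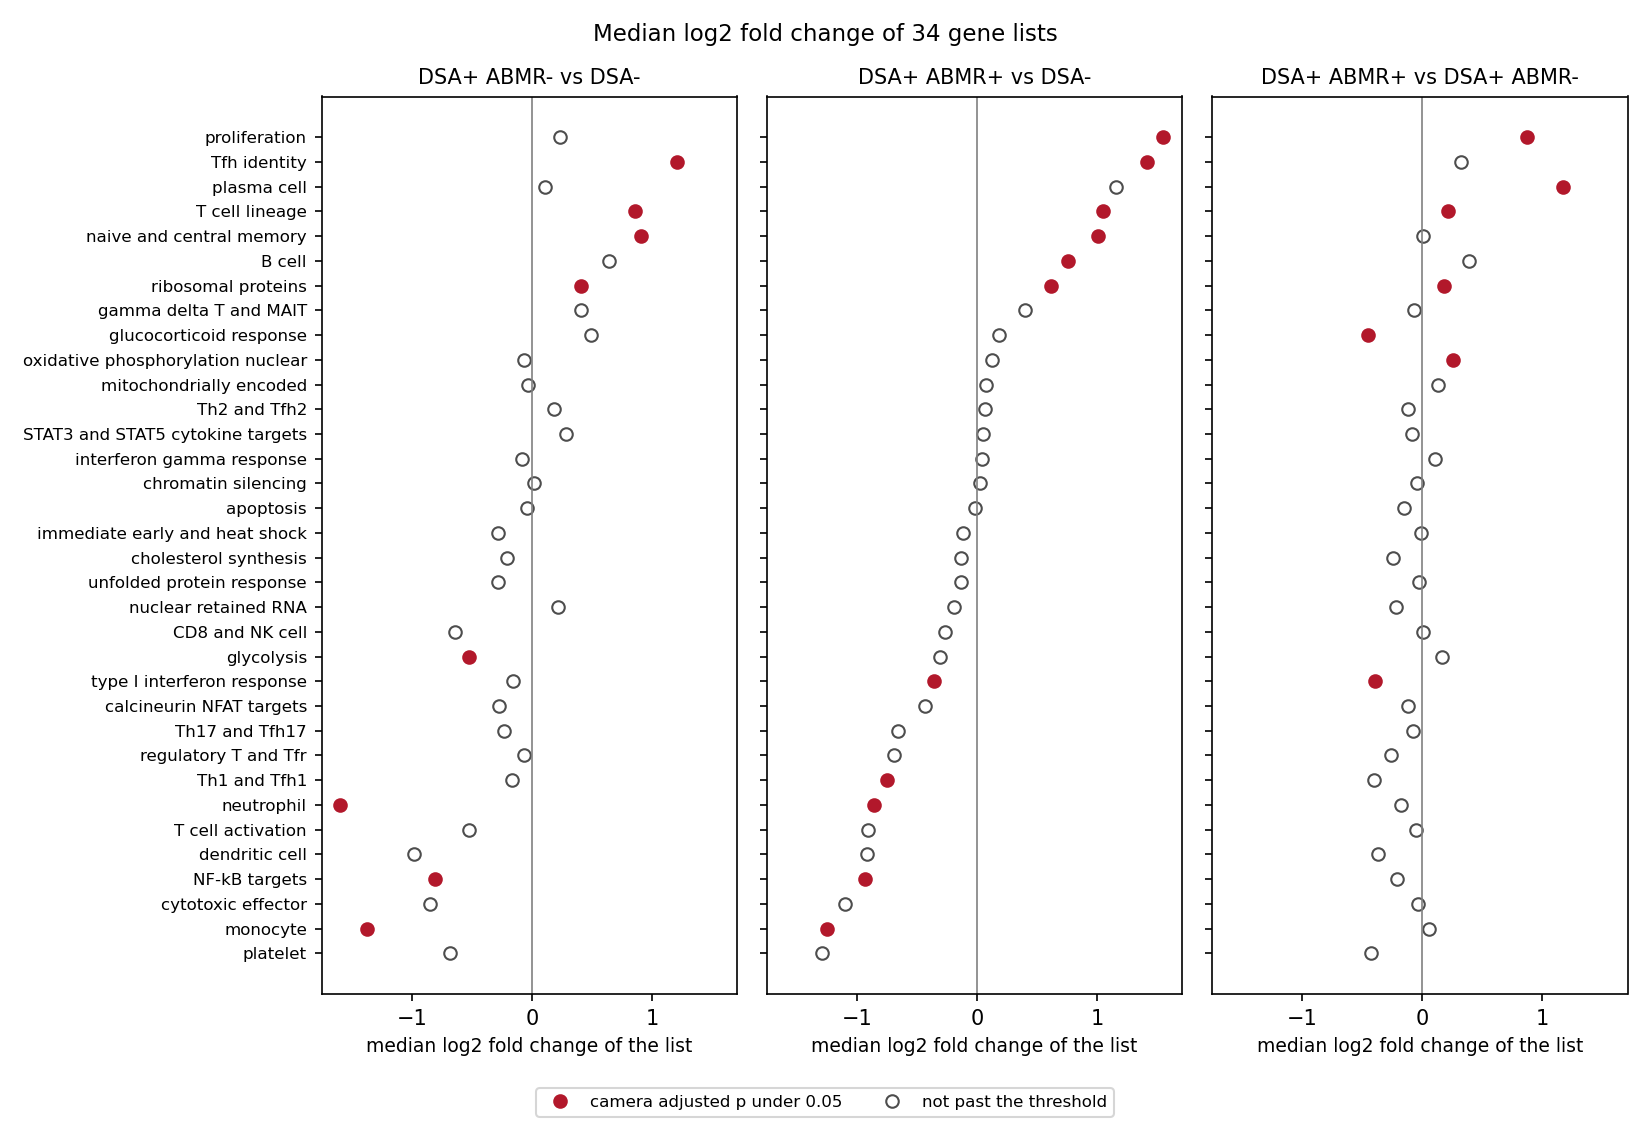
Median log2 fold change (horizontal axis) of the 34 gene lists in the 3 pairwise comparisons; filled points passed camera at an adjusted p below 0.05 and open points did not. The Tfh identity list lies at 1.21 and 1.42 in the comparisons with DSA- and at 0.32 between the DSA+ groups.

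The comparison of DSA+ ABMR+ with DSA+ ABMR- asks how rejection differs among recipients who have the antibody, and no gene passed in edgeR (lowest adjusted p = 0.870, with 1003 genes at an unadjusted p below 0.05 and 969 expected by chance). Tfh markers lay close together: CXCR5 stood at 130 ± 61.9 against 93.6 ± 36.5 CPM (log2 fold change 0.47, SE 0.51), PDCD1 at 13.6 ± 1.51 against 10.7 ± 4.66 CPM (0.34), ICOS at 69.3 ± 12.4 against 65.7 ± 33.2 CPM (0.08) and BCL6 at 84.1 ± 23.1 against 113 ± 43.9 CPM (-0.43). Log2 fold changes were 2.27 for IL21 (SE 2.33), -0.13 for CXCR3, -0.07 for CCR6, 1.32 for MKI67 and 0.77 for CD38. IL21 moved to 4.42 without DSA+ ABMR- replicate 3 and to 1.42 without DSA+ ABMR+ replicate 3, and MKI67 to 0.59 without DSA+ ABMR+ replicate 2. The gene with the lowest p was UCKL1, a uridine kinase gene, at 18.9 ± 2.27 against 5.84 ± 2.14 CPM (1.69, SE 0.34, adjusted p = 0.870). Next came PLA2G16 (-3.06), IGFBP3 (-2.77; -1.94 without DSA+ ABMR- replicate 3), TWF2 (1.12), TSPYL2 (-0.95) and ABCC1 (-0.83), all at an adjusted p of 0.870. Others of the 24 lowest, all at 0.953, were HERC5 (-1.37), IFIT1 (-2.53), RAC2 (0.70), TNFAIP3 (-0.50), RGS1 (-0.75) and SPRY2 (no count against 1.31 ± 1.02 CPM, a log2 fold change of -4.87 or below). DESeq2 called 20 genes, the edgeR likelihood ratio test 7 and limma-voom 0, edgeR without a filter 63, and edgeR without DSA+ ABMR+ replicate 2 called 2. Signs turned for ICOS without DSA+ ABMR- replicate 1 (-0.21) or 2 (-0.002) or DSA+ ABMR+ replicate 2 (-0.07), for CXCR3 without DSA+ ABMR- replicate 3 (0.49), and for CCR6 without DSA+ ABMR- replicate 2 (0.12) or DSA+ ABMR+ replicate 3 (0.21).

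In this comparison 7 lists passed camera, and all gave an adjusted p = 0.929 with an estimated correlation. Proliferation genes had a median log2 fold change of 0.87 (adjusted p = 0.00114), with none of 22 past the threshold singly or adjusted over the list alone. MCM2 stood at 13.9 ± 2.89 against 5.82 ± 1.25 CPM and TYMS at 7.06 ± 4.72 against 2.09 ± 1.23 CPM. The log2 fold change of TYMS moved from 1.753 to 1.054 without DSA+ ABMR+ replicate 2. The plasma cell (1.17), nuclear-encoded oxidative phosphorylation (0.25), T cell lineage (0.22) and ribosomal protein (0.18) lists lay higher by their medians and the type I interferon (-0.39) and glucocorticoid response (-0.46) lists lower, all at an adjusted p of 0.0299. Only the interferon list had genes past the threshold adjusted over the list alone, with 2 fallen. IGKC stood at 17.8 ± 11.1 against 7.92 ± 0.925 CPM, ATP5F1A at 134 ± 22.9 against 91.8 ± 11.9 CPM, CD5 at 231 ± 34.2 against 133 ± 66.9 CPM, RPLP0 at 1012 ± 69.5 against 775 ± 122 CPM and TSC22D3 at 1050 ± 212 against 1365 ± 55.1 CPM. Ribosomal RNA shares were 6.497% and 4.537% in the same groups.

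Each of these 7 calls between the DSA+ groups was lost without DSA+ ABMR+ replicate 2, with adjusted p of 0.400 for proliferation, glucocorticoid response, oxidative phosphorylation, ribosomal protein and plasma cell genes, 0.430 for T cell lineage and 0.663 for type I interferon genes. Without DSA+ ABMR- replicate 1 the proliferation (0.0544), glucocorticoid (0.684), oxidative phosphorylation (0.169), ribosomal protein (0.531) and T cell lineage (0.645) calls were lost. Without DSA+ ABMR- replicate 2 the interferon (0.695), T cell lineage (0.0834) and plasma cell (0.0581) calls were lost, and without DSA+ ABMR- replicate 3 those of oxidative phosphorylation (0.126) and plasma cells (0.224). Leaving out DSA+ ABMR+ replicate 1 ended the oxidative phosphorylation call (0.125), and DSA+ ABMR+ replicate 3 the glucocorticoid (0.0886), plasma cell (0.0886) and T cell lineage (0.0504) calls. Without DSA- replicate 2 the glucocorticoid, oxidative phosphorylation and T cell lineage calls were lost (0.0517 each), and without DSA- replicate 3 the glucocorticoid, oxidative phosphorylation and plasma cell (0.0506 each) and T cell lineage (0.0634) calls. The genes and lists tested changed with the libraries too. The T cell lineage median turned to -0.0088 without DSA+ ABMR- replicate 1, and the plasma cell median was 0.37 without DSA+ ABMR+ replicate 3. The lowest adjusted p over the 9 fits lay between 9.32e-06 (proliferation) and 0.00785 (oxidative phosphorylation). The directional fry test passed for 0 lists.

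The remaining lists passed in no comparison. Medians for DSA+ ABMR- against DSA-, DSA+ ABMR+ against DSA- and DSA+ ABMR+ against DSA+ ABMR- follow in that order. They were -0.85, -1.10 and -0.04 for cytotoxic effector genes, -0.64, -0.26 and 0.01 for CD8 and NK cell genes, -0.98, -0.91 and -0.37 for dendritic cell genes and -0.68, -1.29 and -0.43 for platelet genes. In some fits that leave out 1 library, the median fold changes of the first 2 lists and the platelet list moved by a factor of over 1.5 or turned. The medians ranged over -1.77 to -0.15, -1.68 to -0.48 and -1.13 to 0.79 for cytotoxic effector genes and -1.37 to 0.18, -1.37 to 0.26 and -1.22 to 0.69 for CD8 and NK cell genes. Platelet genes ranged from -1.73 to -0.0949, -2.38 to -0.86 and -0.78 to 0.53. The largest shifts came without DSA- replicate 1 or 3, DSA+ ABMR- replicate 1 or 2 or DSA+ ABMR+ replicate 1. T cell activation genes had medians of -0.52, -0.91 and -0.05, with CD69 risen and ENTPD1 fallen in the first comparison and CD28 risen and ENTPD1 fallen in the second. Th2 and Tfh2 genes had 0.19, 0.07 and -0.12, Th17 and Tfh17 genes -0.24, -0.66 and -0.08, and regulatory T and Tfr genes -0.07, -0.69 and -0.26. Interferon gamma response genes had -0.09, 0.04 and 0.10, calcineurin NFAT targets -0.27, -0.43 and -0.12, and STAT3 and STAT5 targets 0.28, 0.05 and -0.08. Apoptosis genes had -0.04, -0.02 and -0.15, cholesterol synthesis genes -0.20, -0.13 and -0.25, unfolded protein response genes -0.28, -0.13 and -0.03 and chromatin silencing genes 0.02, 0.02 and -0.04. Gamma delta T and MAIT genes had 0.41, 0.40 and -0.07 (-0.22 to 0.82, -0.11 to 0.61 and -0.71 to 0.55 without 1 library), immediate early and heat shock genes -0.28, -0.12 and -0.01, mitochondrially encoded genes -0.04, 0.08 and 0.13 and nuclear retained RNAs 0.22, -0.19 and -0.22.

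Lists that passed in some comparisons only had these medians in the others. Proliferation, plasma cell and B cell genes had 0.24, 0.11 and 0.64 in DSA+ ABMR- against DSA-. Proliferation turned without DSA- replicate 3 or DSA+ ABMR- replicate 3 (range -0.15 to 0.58), plasma cells without DSA- replicate 3 or DSA+ ABMR- replicate 1 (-0.26 to 0.70) and B cells without DSA+ ABMR- replicate 1 (-0.25 to 0.83). Type I interferon, Th1 and Tfh1, glucocorticoid response and oxidative phosphorylation genes had -0.16, -0.16, 0.49 and -0.06 there. In DSA+ ABMR+ against DSA-, glycolysis (-0.31), plasma cell (1.16), glucocorticoid response (0.18) and oxidative phosphorylation (0.12) genes did not pass. In the comparison of the DSA+ groups the Tfh identity (0.32), naive and central memory (0.00), monocyte (0.06), neutrophil (-0.17), B cell (0.39), NF-kB (-0.21), Th1 and Tfh1 (-0.41) and glycolysis (0.17) lists did not pass, the B cell median turning to -0.31 without DSA+ ABMR+ replicate 2. Leaving out 1 library turned the median of 16 of 34 lists in DSA+ ABMR- against DSA-, 9 in DSA+ ABMR+ against DSA- and 16 in DSA+ ABMR+ against DSA+ ABMR-, 1 of them, T cell lineage in the last, a called list. Median, mean and test differed in sign for 4 lists in DSA+ ABMR- against DSA- (Th2 and Tfh2, cholesterol synthesis, CD8 and NK cell, nuclear retained RNA). They did so for 5 in DSA+ ABMR+ against DSA- (Th2 and Tfh2, interferon gamma, glucocorticoid, chromatin silencing, nuclear retained RNA). In DSA+ ABMR+ against DSA+ ABMR- it was 6 lists (T cell activation, Th17 and Tfh17, interferon gamma, CD8 and NK cell, neutrophil, platelet).

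Over the 3 groups together, 411 genes passed the test for any difference. The DSA- group stood apart from the other groups in 369 of them (89.8%), higher in 271 and lower in 98, the DSA+ ABMR- group in 16 and the DSA+ ABMR+ group in 26. Over all 19381 genes tested, the DSA- group was the odd one in 45.6%. DESeq2 called 1625 genes, limma-voom 882 and the likelihood ratio test 1246. The count of 411 was 73 without DSA- replicate 1, 135 without DSA- replicate 2, 17 without DSA- replicate 3, 213 without DSA+ ABMR- replicate 2 and 167 without DSA+ ABMR+ replicate 3. It was 968 without DSA+ ABMR- replicate 1 and 741 without DSA+ ABMR- replicate 3, and with the monocyte score as a covariate 8 genes passed. It was 0 with the ribosomal RNA share as a covariate and 0 without both libraries that lay farthest out.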

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

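The covariates, the length and GC offsets, the thinning and the removal of both libraries farthest out were chosen after the results were seen. The other settings were not. The monocyte score and the ribosomal RNA share followed the groups, so calls lost with either as a covariate do not tell a cause. Scaling (RLE, upper quartile), a filter at 5 CPM, non-robust estimation, protein-coding genes only, the offsets and thinning kept the number of genes within 1.5 times: 229 to 431 against 333 for DSA+ ABMR- against DSA-, 374 to 611 against 508 for DSA+ ABMR+ against DSA-, 276 to 436 against 411 for any difference, and 0 for DSA+ ABMR+ against DSA+ ABMR-. In the order DSA+ ABMR- against DSA-, DSA+ ABMR+ against DSA-, and any difference, the counts moved to 1409, 1697 and 1879 with no filter, 1307, 1660 and 1625 with DESeq2, 836, 1018 and 882 with limma-voom, 826, 1234 and 1246 with the edgeR likelihood ratio test, and 899, 1309 and 1055 at an adjusted p below 0.10. They were 12, 1 and 8 with the monocyte score as a covariate, 2, 0 and 0 with the ribosomal RNA share, and 0, 0 and 0 in edgeR without both libraries farthest out (2144, 2579 and 2138 at an unadjusted p below 0.05). With only the 6 samples of a pair they were 162 and 1066. For DSA+ ABMR+ against DSA+ ABMR- no filter gave 63 genes, DESeq2 20 and the likelihood ratio test 7. Leaving out 1 library gave 41 to 809, 63 to 1053, 0 to 2 (between the DSA+ groups) and 17 to 968 genes. Lists went from 8, 11 and 7 to 0, 0 and 0 with an estimated correlation and to 2, 3 and 0 with directional fry. The monocyte covariate gave 2 and 4 lists in the comparisons with DSA-. Comparing the DSA+ groups, 3 lists passed with the 6 samples alone and 4 without both libraries farthest out. Leaving out 1 library gave 7 to 10, 8 to 15 and 0 to 7 lists. Of 73 called gene results, DESeq2 kept 71, limma-voom 56, RLE factors 72, and leaving out 1 library 14 (DSA- replicate 3) to 71 (DSA+ ABMR- replicate 1). Of the called results 0 changed sign. Leaving out 1 library could hardly turn them, since 333 of 333 and 506 of 508 called genes had no overlap between the groups compared. Uncalled log2 fold changes turned sign 15 times. In DSA+ ABMR- against DSA- these were IL21 (0.11 with limma-voom; -2.39 to 4.76 over the fits without 1 library, positive without DSA- replicate 2 and DSA+ ABMR- replicates 1 and 2), CXCR3 (-0.20 without DSA+ ABMR- replicate 3, up to 0.85) and MKI67 (-0.0482 without DSA- replicate 2, -0.0875 without DSA+ ABMR- replicate 2, up to 0.69). CXCR3 in DSA+ ABMR+ against DSA- lay between -0.0369 (without DSA- replicate 2) and 0.64. For DSA+ ABMR+ against DSA+ ABMR-, ICOS lay between -0.21 and 0.52 (negative without DSA+ ABMR- replicates 1 and 2 and DSA+ ABMR+ replicate 2), CXCR3 between -0.59 and 0.49 (positive without DSA+ ABMR- replicate 3; 0.10 with limma-voom), and CCR6 between -0.45 and 0.21 (positive without DSA+ ABMR- replicate 2 and DSA+ ABMR+ replicate 3). For all of these changes the cause was not tested. No paired analysis was possible because replicate numbers only name samples of different groups. At 17001823 to 26809573 gene counts per library thinning changed little.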

Other observations

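Histone genes and small nucleolar RNAs, both looked at after their values were seen, were higher in the DSA+ groups. Of 61 protein-coding histone genes tested, 10 rose and 0 fell in DSA+ ABMR- against DSA- (median log2 fold change 0.91, camera adjusted p = 4.35e-17; adjusted p = 0.130 with an estimated correlation). In DSA+ ABMR+ against DSA-, 18 rose and 0 fell (median 1.07, adjusted p = 2.14e-21; adjusted p = 0.130 with an estimated correlation). HIST1H2AE stood at 75.0 ± 16.9 CPM in DSA-, 174 ± 32.0 CPM in DSA+ ABMR- and 158 ± 17.5 CPM in DSA+ ABMR+ libraries (n = 3 each; edgeR adjusted p = 0.0177 for the last against the first), and HIST1H2BD at 129 ± 36.8, 271 ± 47.7 and 260 ± 24.8 CPM (adjusted p = 0.025). From DSA+ ABMR- to DSA+ ABMR+, edgeR called 0 of the 61, with a median of 0.16 (camera adjusted p = 0.0228; adjusted p = 0.567 with an estimated correlation). Histone genes share reads with their paralogs, so single values are uncertain. Monocyte marker sums were 14221, 5294 and 5461 CPM in DSA-, DSA+ ABMR- and DSA+ ABMR+ libraries, and a cause of the rise was not tested.

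Of 168 small nucleolar RNAs tested, 5 rose and 0 fell in DSA+ ABMR- against DSA- (median 0.52, camera adjusted p = 3.50e-07; adjusted p = 0.320 with an estimated correlation). In DSA+ ABMR+ against DSA-, 22 rose and 0 fell (median 1.05, adjusted p = 1.58e-21; adjusted p = 0.130 with an estimated correlation). SNORD105B stood at 22.5 ± 4.33, 53.3 ± 9.48 and 77.3 ± 30.9 CPM in DSA-, DSA+ ABMR- and DSA+ ABMR+ libraries (log2 fold change 1.78, SE 0.28, adjusted p = 0.0103 for the last against the first), and SNORD3C at 221 ± 40.5, 427 ± 75.7 and 416 ± 34.1 CPM. Between the DSA+ groups the median was 0.55, with 144 of 168 positive and 0 called by edgeR (camera adjusted p = 2.54e-13; adjusted p = 0.193 with an estimated correlation). Ribosomal RNA shares were 3.604%, 4.537% and 6.497% in the same order of groups. These p-values are adjusted over the 6 tests of both families.

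Of the tests in the following paragraphs, those of length and GC content, of the T cell share, of B cell RNA and of a single library were chosen after the results they measure were seen.

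In both DSA+ groups more genes were lower than higher against DSA- (211 of 333 and 331 of 508). For DSA+ ABMR- this turned with upper-quartile factors (129 of 296), without DSA- replicate 2 (84 of 180) and without DSA+ ABMR- replicate 2 (30 of 61) or 3 (16 of 41), and with a covariate 0 were lower in either group. Gene length and GC content are argued against as the whole of it in DSA+ ABMR+ only: offsets for both left 94.7% of the median log2 fold change of the 331 genes called lower in DSA+ ABMR+ (-1.30 before, -1.24 after). With the offsets 344 of the 508 genes stayed called (67.72%). The same median was not taken for DSA+ ABMR-. Monocyte RNA in the sorted samples may account for the pattern: with group means removed, 93.05% of these 331 genes covaried positively with the monocyte score over the 9 libraries, a share that 3 of 216 rearrangements within groups reached (exact p = 0.0139), against 48.06% of all tested genes. It may bear on the genes called higher too. Of the 177 higher in DSA+ ABMR+, 89.83% covaried negatively with the score (8 of 216 rearrangements, exact p = 0.0370). Of the 122 higher in DSA+ ABMR-, 78.69% did (13 of 216, exact p = 0.0602). RNA quality stays open, since 58.91% of the 331 lower genes covaried negatively with the ribosomal RNA share (97 of 216 rearrangements reached it) and that share follows the groups, and a biological difference between the patient groups was not tested apart from these.

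CXCR5 stood higher in DSA+ ABMR- (adjusted p = 0.0905, not called) and DSA+ ABMR+ (0.0466, called in 3 of 9 fits without 1 library) than in DSA-, as did the Tfh identity list (medians 1.21 and 1.42; adjusted p = 0.487 and 0.434 with an estimated correlation). A larger share of T cell RNA alone is argued against for CXCR5, whose log2 ratio to the summed T cell lineage list was higher by 1.674 in the 6 DSA+ than in the 3 DSA- libraries (one-sided exact permutation p = 0.0119, the lowest that 84 arrangements allow). CD4 took 281, 371 and 300.8 of 1303, 1608 and 1256 CPM of this sum in the DSA- libraries. In DSA+ ABMR- libraries it took 263.9, 246.4 and 261 of 1510, 1962 and 2983 CPM. In DSA+ ABMR+ libraries it took 249.3, 315.1 and 276.7 of 2310, 3078 and 2342 CPM. CD4 thus did not rise with the sum. The ratio without CD4 was not taken, so the size of 1.674 is uncertain. For the Tfh identity list as a whole another measure was taken, the mean log2 CPM of its genes minus that of the T cell lineage genes. It was higher by 0.319 in the DSA+ libraries (exact permutation p = 0.0595 one-sided, 0.107 two-sided) and leaves this open. The Tfh identity sum was 1.535 and 1.803 times its DSA- level in DSA+ ABMR- and DSA+ ABMR+, and the T cell lineage sum 1.549 and 1.855 times. By the sums, the list thus rose about as much as the T cell lineage genes. B cell RNA, which holds CXCR5 too, is argued against as the whole of this, since the log2 ratio of CXCR5 to the summed B cell list was higher by 1.672 (exact p = 0.0238, reached by 2 of 84 arrangements), while a share of it stays open, as the B cell sums were higher by 0.8096 and 0.6051 of the CPM by which CXCR5 was in DSA+ ABMR- and DSA+ ABMR+ against DSA-. The rises of CXCR5 and of the T cell lineage and B cell sums had been seen when the ratios of CXCR5 were chosen. The ratios therefore restate those rises and are no separate tests. A difference in the Tfh cells themselves remains a hypothesis, and with the monocyte score as a covariate the log2 fold change of CXCR5 was 0.77 (SE 0.64) in place of 2.08 (SE 0.53) in DSA+ ABMR- and 1.33 (SE 0.65) in place of 2.55 (SE 0.54) in DSA+ ABMR+, where the smaller fold and larger SE ended the call. The monocyte score followed the groups, so this fit cannot tell a monocyte share from another difference between the groups.

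The proliferation list was higher in DSA+ ABMR+ than in DSA+ ABMR- with camera (adjusted p = 0.00114; adjusted p = 0.929 with an estimated correlation and 0.803 with directional fry). One library could account for this call, since without DSA+ ABMR+ replicate 2 its adjusted p was 0.4, and it was lost without DSA+ ABMR- replicate 1 too (0.0544). Dividing plasma cells could not be told apart, as the correlation within groups of the proliferation score with the plasma cell sum was 0.4417 over the 9 libraries (exact p = 0.208). The sum is a weak measure of plasma cells. XBP1, which is in the unfolded protein response list too, took 98.91, 120.4 and 68.92 of its 251.6, 386.6 and 272 CPM in the DSA+ ABMR+ libraries. IGKC took 5.5, 27.08 and 20.94 CPM there, so the correlation cannot decide the question. A biological difference with rejection remains open and was not tested apart from these.

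Other splits of the samples were counted as well. For the pairs of groups the 10 splits of 6 samples are too few for a share below 0.05. The real split gave 333 genes and 8 lists in DSA+ ABMR- against DSA-, with 1 gene and 13 lists as the highest of the others, so 1 split for genes and 3 for lists were as large, the real one included. In DSA+ ABMR+ against DSA- the real split gave 508 genes and 11 lists, with 0 and 15 as the highest of the others, and 1 and 3 splits as large. For the DSA+ groups it gave 0 genes and 7 lists, with 17 and 10 as the highest of the others, and 10 and 5 splits as large. For any difference among the 3 groups, 3 of 100 drawn splits gave 411 genes or more, the real one included. That share is below 0.05 and argues against a random split of all 9 libraries as the source of the count. The others as large gave 830 and 1044 genes, kept the 3 DSA- libraries together and mixed those of the DSA+ groups. The count thus speaks to the DSA- group against the rest and cannot tell the DSA+ groups apart. The 6 drawn splits that keep the 3 DSA- libraries together were the 6 with at least 100 genes, and 85 of the 100 gave 0.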
